A study of Pyrus pyrifolia with 6 samples.

How the data were processed

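Genomic DNA was taken from fruit skin of 'Cuiguan' pear with a CTAB method, from 3 biological replicates of unbagged and 3 of bagged fruit at 115 days after full bloom, per the labels' protocols. Fruit of the bagged group was covered with single-layer white bags at 20 days and double-layer yellow-white bags at 40 days, on trees of 7 years. Libraries for bisulfite sequencing were made with the Accel-NGS Methyl-Seq kit, per the labels' protocols. This kit builds libraries from DNA already treated with bisulfite and adds a short tail of low complexity to the fragments. Untrimmed tails can bias methylation calls near read ends, and whether they were trimmed is not given in the sources used here. Bismark version 0.16.3, which aligns bisulfite reads and calls methylation, and FastQC are named in the submitters' processing notes. The region caller, its thresholds, the genome build and the rate of bisulfite conversion are not given in the sources used here. Positions are printed as the authors' table gives them, with both ends included, since every length equals end minus start plus 1. They were read as counted from 1, which the sources used here do not state.

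The authors' deposited table lists 53954 regions in 3 contexts on 17 chromosomes and 192 unplaced scaffolds, and no region occurs more than once in a context. Per the file headers, it holds the mean methylation level of each region as a fraction between 0 and 1 for the bagged and for the unbagged group, with the replicates combined. The groups were read from column names that begin as the sample titles do, so that the column of unbagged means is not a column of the CG context. Levels are printed here as percentages. The deposited difference equals the bagged minus the unbagged mean in every region (within 1e-09). The area statistic is named but not explained in the file headers, and was read as a score of the authors' caller. It has the sign of the difference in all but 2 CHH regions, so the sign of the difference was used for direction. Regions had at least 51 bp and at least 4 cytosines of their context. The authors chose the regions for their difference in these samples, so a region's difference is subject to selection and the table does not describe the methylome outside the called regions. A shift of the thresholds or of the depth between contexts would change how many regions each context holds. CHH cytosines are more frequent, so CHH regions can be called on smaller differences. For this reason the numbers of regions in different contexts describe the table and were not tested against each other.

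Coverage was not used here, so the depth behind a level is unknown and no error can be given for a single region. No values per sample were used, so no test across replicates was made. Such a test of 3 against 3 samples could not give a two-sided exact permutation p below 0.1. Shares have 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only. Tests between regions permuted directions in blocks: regions of 1 Mb bins were kept together and the bins put in random order 10000 times (two-sided unless said otherwise, seed 1), so that runs of neighbouring regions with the same direction do not count as independent. The smallest p these permutations can give is 0.0001. For chromosomes the statistic was a chi-square over chromosomes, with large values counted. For overlap it was the number of pairs sharing at least 1 bp and direction, for scaffolds the difference in share, and for the size of differences the difference of medians with context labels permuted. The 16 tests were adjusted together by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. For overlap by direction the statistic was the difference in share overlapping between higher and lower regions. The tests of the CHH median against the other contexts, and those of overlap by direction, are counted among them but not used. The calling of regions sets the outcome of the former. As overlapping regions mostly shared direction, the direction splits of the contexts bear on the latter.

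The procedures were first tested on simulated data at the real positions, with 100 simulated sets per setting. With no chromosome effect, 6% of CG, 4% of CHG and 2% of CHH sets were called. With chromosomes set 20 points apart in CG or CHG context, or 5 points apart in CHH context, 100% were called. For overlapping CG and CHH regions, 3% of sets with independent directions and 91% of sets with 20% of the pairs forced to share direction were called. For CG and CHG regions 2 to 20 kb apart the corresponding figures were 7% and 94%. In both simulations of pairs, each CG direction was drawn independently of its neighbours. These rates therefore do not cover runs of neighbouring regions with the same direction. Circular shifts called 7% of sets with random positions and the comparison of chromosome middles with ends called 9%. Both called 100% when a signal was planted. Numbers of overlaps were checked against bedtools 2.31.1. Computation used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

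The comparisons and the rule for named items were fixed before the data were examined. The rule asked, per context, for the 5 largest gains and the 5 largest losses among regions in a gene body or promoter with at least 10 cytosines, scaffolds included, plus regions from lists of genes. A genome annotation was not used here, so the rule was applied to all regions with at least 10 cytosines. The planned counts of genes with a region, the split by genomic feature and the tests of gene lists (suberin and cutin, phenylpropanoids, peroxidases, flavonoids, transcription factors, hormones, light signalling, photosynthesis, cell wall, methylation machinery, sugar transport and ribosomal proteins) were not run for the same reason. The comparison of scaffolds with chromosomes and the split by mean level were added after the data were seen. For overlap, the plan named CG regions against CHG and CHH regions. The pairs of CHG and CHH regions, the overlap counted by direction and the combinations of all contexts went beyond it. Alternatives tried were differences of at least 20 or 30 points, at least 10 cytosines, the larger area statistics, weighting by length, chromosomes only, merging within 500 bp, an overlap of at least 50% of the shorter region, and, added later, bins of 100 kb and 5 Mb and leaving out each chromosome in turn. For the median differences, the limit of 10 cytosines and the restriction to chromosomes were also added later.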

Results

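DNA methylation was measured by whole-genome bisulfite sequencing, which reads unmethylated cytosines as thymine, in the fruit skin of the pear Pyrus pyrifolia 'Cuiguan'. The skin of this cultivar turns partly russet, that is, parts of its surface become brown and corky. The design sets skin of fruit grown in paper bags (bagged, 3 samples) against skin of fruit left uncovered (unbagged, 3 samples), to ask how the methylome of the skin differs between fruit grown with and without a bag in relation to russeting. The fruit came from trees of 7 years, single-layer bags were used at 20 and double-layer bags at 40 days after full bloom, and all skin was taken at 115 days. The values are those of the authors' deposited table of 53954 differentially methylated regions, with 1 mean methylation level per group and region. The replicates are combined in these means, so no value below has a spread between replicates, and the sequencing depth behind it is unknown. Methylation was called separately for cytosines in CG, CHG and CHH context, where H is A, C or T. Every region was called as different by the authors, so the comparisons below are between regions: in which context, in which direction, by how much and where.

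The first comparison was the direction of the difference in each context. Most regions were in CHH context and had more methylation in bagged skin, whereas in CG context the lower regions were more numerous and in CHG context both directions were about equal in number. CHH context held 50043 regions, 92.8% of the table, of which 45290 were higher and 4753 lower in bagged than in unbagged skin. This is a share of 90.5% higher (95% exact binomial interval 90.2 to 90.8). CG context held 2030 regions, 792 higher and 1238 lower, a share of 39.0% higher (36.9 to 41.2). Of the 1881 CHG regions, 962 were higher and 919 lower, which is 51.1% (48.9 to 53.4). In sequence covered, the CHH regions higher in bagged skin spanned 6545 kb and the lower ones 524 kb, while CG regions spanned 91.2 kb and 135 kb and CHG regions 109 kb and 103 kb. The intervals cover counting error only, since regions are not independent replicates of the treatment.

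The excess of higher CHH regions was smaller among regions with large differences in percentage points, but not among those with a large area statistic. Among the 5027 CHH regions with a difference of at least 20 percentage points, 78.5% were higher in bagged skin (77.4 to 79.7), and among the 949 with at least 30 points, 69.97% (66.9 to 72.9). Among the 25022 with the larger absolute area statistic, 94.1% were higher (93.8 to 94.4). Higher CHH regions also held more cytosines, a median of 36 against 24 in the lower ones. A limit on the area statistic may therefore also select regions with more cytosines, which was not tested. The share in CG context was 35.9% at 20 points or more, and that in CHG context was 46.8%, on the other side of an equal split from the 51.1% of all CHG regions.

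**Figure D1:**
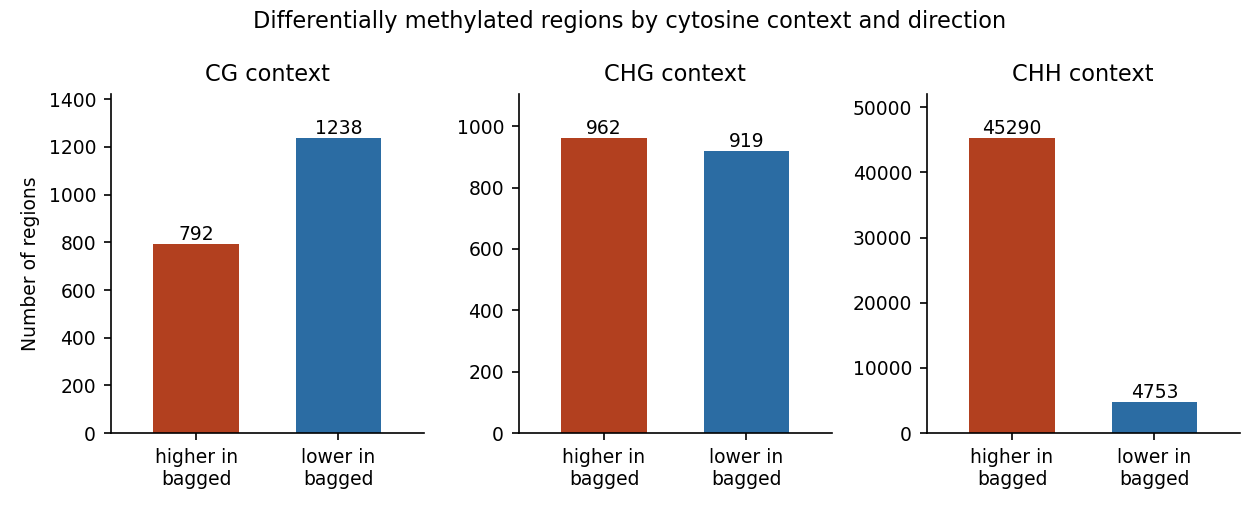
Bars give the number of regions (vertical axis, on a separate scale for each context) that were higher or lower in bagged than in unbagged skin in CG, CHG and CHH context. The 45290 higher CHH regions outnumber all other classes, and CG is the context in which lower regions, 1238, outnumber higher ones, 792.

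The second comparison was the size of the difference and the methylation level at which it occurred. CHH regions changed from low levels: the authors' mean level of the higher CHH regions had a median of 11.1% in unbagged skin and 23.7% in bagged skin, a median ratio of 1.97 (quartiles 1.66 and 2.53). Of these regions, 20598 (45.5%) had a level under 10% in unbagged skin. The lower CHH regions had medians of 25.3% in unbagged and 9.26% in bagged skin. CG regions higher in bagged skin had medians of 27.2% unbagged and 55.5% bagged, and those lower in bagged skin 64.2% unbagged and 34.5% bagged. CHG regions were close to these, with 27.1% and 55.6% for the higher and 60.4% and 29.7% for the lower regions.

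In percentage points, the median difference was 22.2 for higher (quartiles 16.8 and 28.1) and -23.7 for lower CG regions (-29.0 and -18.8). It was 22.5 (18.04 and 29.5) and -24.4 (-30.7 and -20.1) in CHG context. In CHH context it was 11.5 (8.23 and 15.0) for higher and -13.8 (-19.3 and -9.66) for lower regions. The median absolute difference of CG regions, 23.2 points, and that of CHG regions, 23.6 points, did not differ beyond chance (two-sided block permutation of the context labels, p = 0.1168, adjusted p = 0.133). Both medians are of regions called for their difference with unknown thresholds, so they are not read as equal effects. The CHH median was 11.6 points. CHH regions rested on more cytosines, with a median of 34 against 11 in CG and 10 in CHG context, so that smaller differences can be called in them and their median is not read as a smaller effect. They were also longer, with a median of 122 bp against 93 and 94 bp. Within CHH context, the higher regions had a median length of 126 bp and the lower ones 93 bp.

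The split by direction was also set out by methylation level, taken as the mean of both groups. In CHH context the share of higher regions was 90.8% at a mean level under 10%, 90.2% from 10 to 30%, 90.5% from 30 to 50%, and 93.7% from 50 to 70%. In CG context it fell from 73.9% of 69 regions under 10% (61.9 to 83.7) over 40.5% of 563 regions from 30 to 50% (36.4 to 44.7) to 28.2% of 393 regions from 70 to 100% (23.8 to 33.0). The corresponding CHG shares were 69.0% of 42 regions, 53.4% of 618 and 41.6% of 214.

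**Figure D2:**
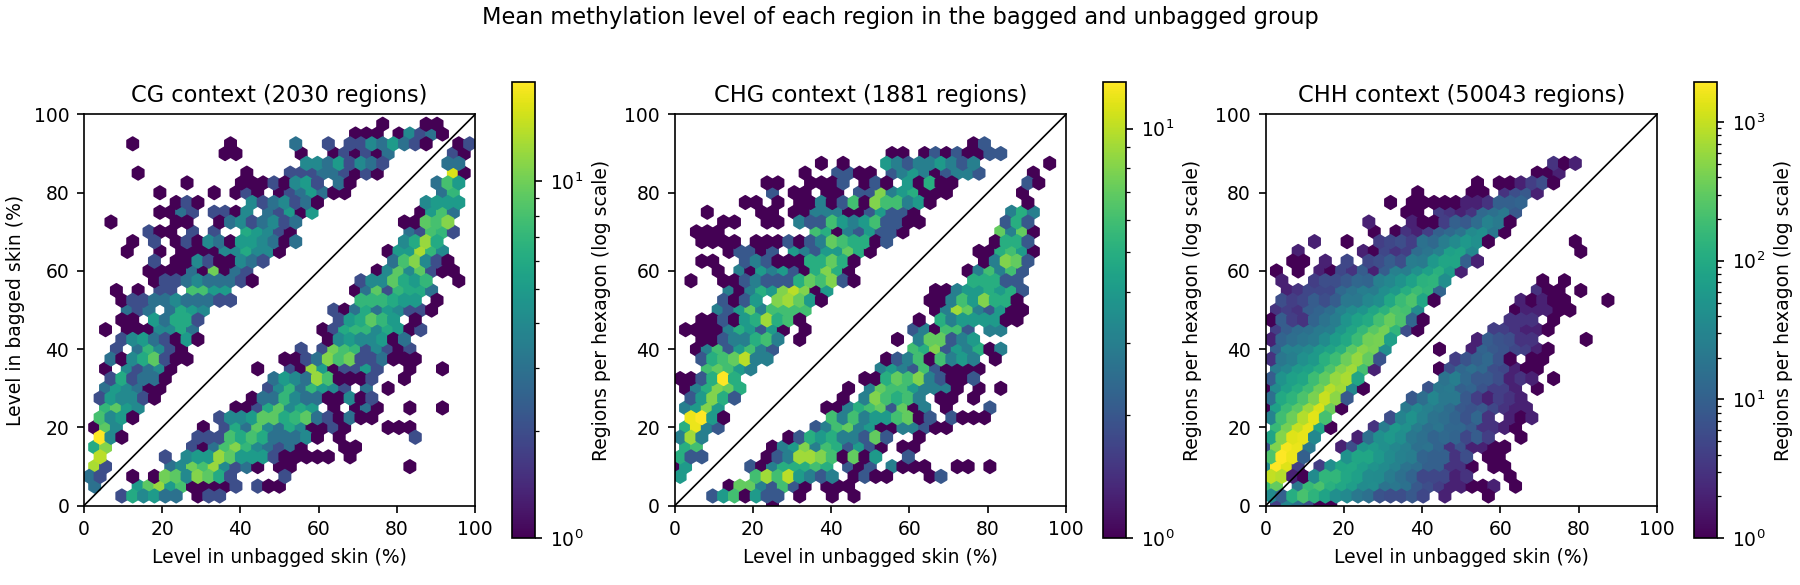
Each panel plots the authors' mean methylation level of a region in bagged skin (vertical axis, %) against that in unbagged skin (horizontal axis, %) for a cytosine context, with colour giving the number of regions per hexagon on a log scale that differs between panels. Points above the line of equality are higher in bagged skin: in CHH most regions lie above it at low levels, with medians of 11.1% unbagged and 23.7% bagged for the higher regions, while CG and CHG regions spread over the whole range of levels on both sides.

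The largest differences were then taken per context and direction among regions with at least 10 cytosines, with positions as the authors' deposited table gives them. In CG context the region with the largest gain among these was on chromosome 11 from 5650253 to 5650431, with 12 cytosines at 72.8% in bagged and 8.33% in unbagged skin. The next were on scaffold_352 from 71893 to 71993 (60.0 points), on chromosome 5 from 25831619 to 25831771 (54.6 points), on chromosome 7 from 6449068 to 6449160 (54.3 points) and again on chromosome 5 from 9607797 to 9607916 (54.1 points), by the deposited differences. The largest CG loss among these in the authors' deposited table was on chromosome 7 from 1528337 to 1528444, with 19.6% bagged and 81.5% unbagged. Losses of -57.5, -56.8, -53.0 and -50.2 points followed, on chromosome 3 from 5742771 to 5742864, on chromosome 5 from 19933652 to 19933740, on chromosome 11 from 11091836 to 11092168 and on chromosome 5 from 10958975 to 10959077.

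Among CHG regions with at least 10 cytosines, the authors' deposited table had its largest gain at the same place on chromosome 11, from 5650234 to 5650459, where 33 cytosines had 69.5% in bagged and 6.62% in unbagged skin. Further CHG gains of 58.7, 58.2, 55.8 and 53.1 points lay on scaffold_677 from 3717 to 3850, chromosome 15 from 35817907 to 35818042, chromosome 17 from 14613599 to 14613761 and chromosome 11 from 12223533 to 12223630. The largest CHG loss among such regions was on chromosome 10 from 10145806 to 10145921, at 21.5% bagged and 76.8% unbagged in the authors' deposited table. It was followed by scaffold_649 from 92619 to 92811 (-52.8 points), chromosome 13 from 11501124 to 11501257 (-49.5 points) and from 865616 to 865797 (-49.1 points), and chromosome 3 from 16877096 to 16877201 (-48.7 points).

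Among CHH regions with at least 10 cytosines, the largest gain was on chromosome 13 from 19035947 to 19036058, where 12 cytosines had 59.8% in bagged and 3.22% in unbagged skin in the authors' deposited table. Gains of 56.6, 55.8, 55.6 and 55.5 points were on chromosome 8 from 5055223 to 5055361, chromosome 17 from 3237519 to 3237713, chromosome 13 from 11182176 to 11182386 and chromosome 7 from 3477244 to 3477358. For the largest loss among such CHH regions, the authors' deposited table gave 3.32% bagged and 55.8% unbagged on chromosome 5 from 14226354 to 14226532. Losses of -51.9, -51.8, -49.5 and -48.3 points were on chromosome 5 from 4055845 to 4055956, chromosome 8 from 18414661 to 18414888, chromosome 2 from 15752376 to 15752459 and chromosome 3 from 8561410 to 8561576. Genes and other features at these positions were not analysed here, and with the depth unknown no error can be set beside them.

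The third comparison asked whether the contexts changed together where their regions overlapped. They did so in CG and CHG context without exception: 288 CG regions (14.2%) shared at least 1 bp with a CHG region, and in all 297 overlapping pairs both regions differed in the same direction, 158 pairs higher and 139 pairs lower in bagged skin. With the CG directions permuted in blocks of 1 Mb, 49.2% of pairs shared direction. Of the 233 overlapping pairs of CG and CHH regions, 195 (83.7%, exact binomial interval 78.3 to 88.2) shared direction against 45.2% under permutation. Among them, 131 pairs were higher in both contexts and 64 lower in both, while in 37 pairs the CG region was lower and the CHH region higher, and 1 pair was the reverse. Of the 223 pairs of CHG and CHH regions, 210 (94.2%, 90.2 to 96.9) shared direction against 50.6%. All 3 excesses had a two-sided permutation p of 0.0001, the smallest possible (adjusted p = 0.00018). At a difference of at least 30 points, a single pair of CHG and CHH regions was left, which gives no test, and 6 pairs of CG and CHH regions, of which 5 shared direction (unadjusted permutation p = 0.0483).

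Counted by direction, a CHH region overlapped 16.4% of the higher and 8.16% of the lower CG regions, and 16.6% of the higher and 6.64% of the lower CHG regions. Since overlapping pairs mostly shared direction and 45290 CHH regions were higher against 4753 lower, higher CG and CHG regions had more possible partners, and these shares are given as a description. Of the higher CG regions 19.2% overlapped a CHG region, and of the lower ones 11.0%. Since all overlapping pairs of CG and CHG regions shared direction, these shares are likewise a description. The overlapping CG regions, 152 higher and 136 lower, were split nearly as evenly as the 962 higher and 919 lower CHG regions. All CG regions, with 792 higher and 1238 lower, were not. A CG region overlapped 16.2% of the higher and 15.0% of the lower CHG regions. The gap among CG regions therefore goes with the larger number of lower CG regions and is not read as a separate result.

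A region of every context shared common positions in 57 combinations, built on 54 CG regions. In 40 of them all contexts were higher in bagged skin, in 15 all were lower, and 2 were mixed. The combination with the largest mean difference, on chromosome 11 from 5650210 to 5650468, contains the leading CG and CHG gains named above, and its 76 CHH cytosines had 14.6% in bagged and 1.98% in unbagged skin in the authors' deposited table. On chromosome 10 from 22770791 to 22770909, the deposited differences were 44.9 points in CG, 40.6 in CHG and 19.5 in CHH context. The combination with the largest common loss lay on chromosome 4 from 9434397 to 9434938, with -41.8, -32.8 and -14.7 points in the authors' deposited table. Both mixed combinations, on chromosome 6 from 16504937 to 16505327 and on chromosome 16 from 17460767 to 17461062, had lower CG and CHG and higher CHH methylation in bagged skin. In the deposited values, the differences at the first were -42.1, -24.0 and 20.2 points. These combinations were picked after their values were seen.

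**Figure D3:**
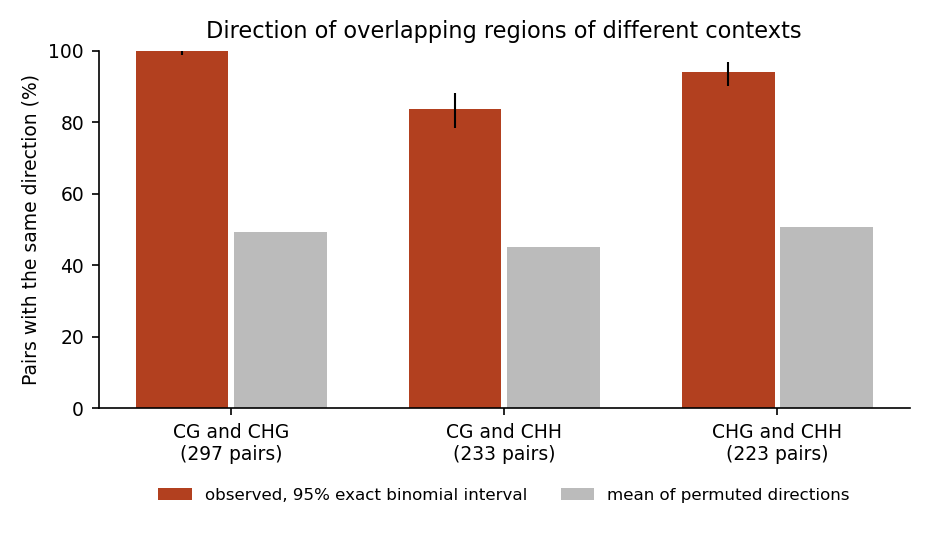
Bars give the share of overlapping region pairs (vertical axis, %) in which both contexts differed in the same direction, with the 95% exact binomial interval, beside the mean share after permutation of directions in 1 Mb blocks. The observed shares are 100% of 297 CG and CHG pairs, 83.7% of 233 CG and CHH pairs and 94.2% of 223 CHG and CHH pairs, against 49.2, 45.2 and 50.6% under permutation.

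The fourth comparison was between chromosomes. The preponderance of higher CHH regions was found on all 17 chromosomes, with shares from 88.5% on chromosome 2 to 91.6% on chromosome 8 and densities of 90.0 to 100.8 CHH regions per Mb. In CG context 24.7% of the regions were higher in bagged skin on chromosome 1 (20 of 81 regions) and 29 of 116 on chromosome 16, against 50.4% on chromosome 5 (71 of 141) and 47.9% on chromosome 3 (67 of 140). On 16 of the 17 chromosomes fewer than 50% of the CG regions were higher. This spread between chromosomes exceeded that of directions permuted in 1 Mb blocks (permutation p = 0.0032, adjusted p = 0.0047). The CHG shares, from 41.3% on chromosome 13 to 59.7% on chromosome 11, varied no more than by chance (permutation p = 0.5067), and the spread of CHH shares did not pass the threshold (permutation p = 0.0697, adjusted p = 0.086), although it did with blocks of 100 kb (permutation p = 0.0039).

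Regions on unplaced scaffolds were higher in bagged skin more often than those on chromosomes in each context. In CG context 41 of 72 scaffold regions were higher (56.9%, exact binomial interval 44.7 to 68.6), against 38.4% of 1958 on chromosomes (permutation p = 0.0063, adjusted p = 0.0084). For CHG the shares were 64 of 94 (68.1%, 57.7 to 77.3) and 50.3% of 1787 (permutation p = 0.0027, adjusted p = 0.0043). For CHH they were 93.5% of 3382 (92.6 to 94.3) and 90.3% of 46661, with a permutation p of 0.0001 (adjusted p = 0.00018). Scaffold CHH regions had a median level of 6.36% in unbagged and 13.8% in bagged skin, against 12.8% and 23.1% on chromosomes.

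**Figure D4:**
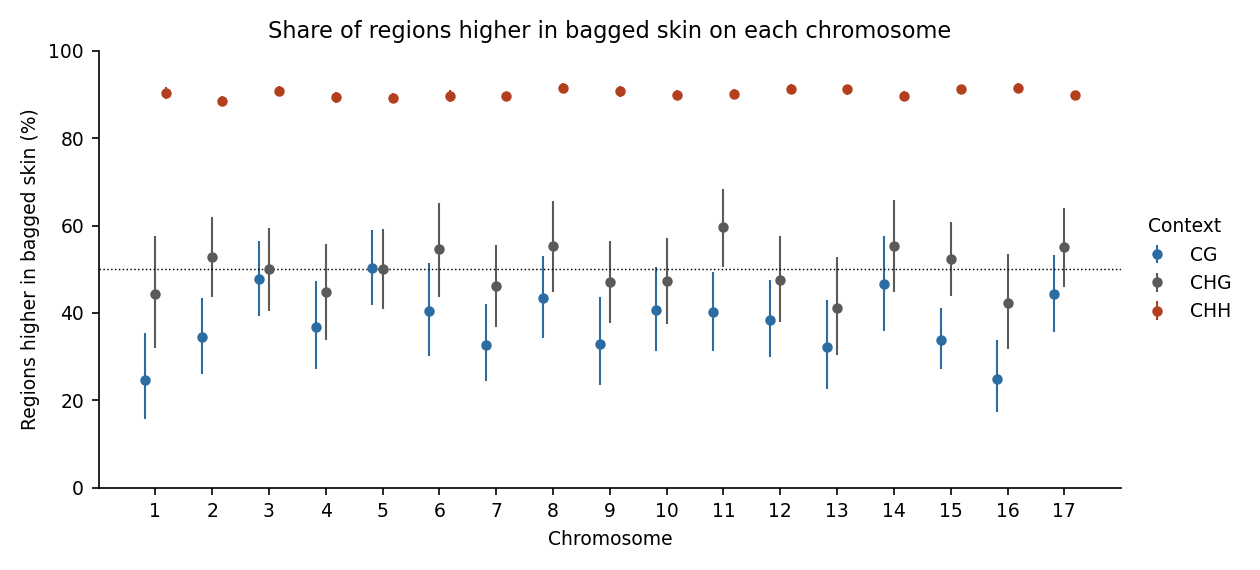
Points give the share of regions higher in bagged skin (vertical axis, %) on each of the 17 chromosomes (horizontal axis) in CG, CHG and CHH context, and bars the 95% exact binomial interval, which covers counting error only. CHH shares lie between 88.5 and 91.6% on all chromosomes, CG shares between 24.7 and 50.4%, and CHG shares between 41.3 and 59.7%, and the dotted line marks 50%.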

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

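Of 211 alternative values, 185 stayed within the limits set for them: the binomial interval for a share, a factor of 1.5 for a number of regions, the quartiles for a median, and the same side of an unadjusted p of 0.05 for a test. Every value with a chromosome left out is among the 185. Numbers of regions could not pass their limit in that way, so the tally is not read as a measure of stability. None reversed a called direction (CHG, whose interval spans an equal split, went to its other side). The bins of 100 kb and 5 Mb, the omission of single chromosomes and the alternatives for medians were chosen after seeing the data. At a difference of at least 20 points, the share of higher regions was 35.9% in CG (1337 regions), 46.8% in CHG and 78.5% in CHH context (5027 regions). At 30 points it was 47.0% in CHG (481 regions) and 69.97% in CHH (949 regions), and 440 CG regions were left. With at least 10 cytosines, CG kept 1186 regions, CHG 956 with 53.5% higher, and CHH had 90.9% higher. The CHG intervals excluded an equal split on opposite sides, with 44.1 to 49.5 at 20 points and 50.2 to 56.7 with at least 10 cytosines. The direction of CHG regions therefore depends on the limit chosen. For regions with the larger area statistic the share was 41.8% in CG and 94.1% in CHH. For CHH it was 89.8% after merging and 92.6% by length. The falls in number follow from the stricter limits, and the cause of the shifts in share was not tested. At 30 points, 100% of CHG and CHH pairs shared direction, but with 1 pair (permutation p = 1). The 3.05-point range of CHH shares between chromosomes passed the threshold with 100 kb bins (permutation p = 0.0039) and not with 5 Mb bins (permutation p = 0.6405). Without each chromosome in turn, the shares were 38.2 to 39.9% in CG, 50.5 to 51.6% in CHG and 90.4 to 90.6% in CHH context, and the spread of CG shares between chromosomes stayed past the threshold, with a permutation p of at most 0.0241 (without chromosome 5 or 16), as it did with 5 Mb bins (permutation p = 0.0307). No paired analysis was possible because the columns hold group means without replicate numbers. For the same reason no replicate was left out, no coverage minimum was varied and no other split of the samples was made. The alternatives for genes, promoters and features were not run, since no annotation was used here. Unknown depth limits every single region.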

Other observations

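In this part, the tests of bisulfite conversion, methylation level, number of cytosines, chromosome position and mean level on scaffolds, and those of pairs other than CG and CHG at 2 to 20 kb, were chosen only after the result was seen. Those of CG and CHG pairs at 2 to 20 kb, of single scaffolds and of circular shifts were also added after the data were first examined, but before their own results were seen. CHH regions higher in bagged skin were denser in the middle of chromosomes than near the ends. The middle 20% of the 17 chromosomes held 9453 of them and the outer 10% at both ends together 7401, a ratio of 1.28, and the middle held more on each of the 17 chromosomes (exact two-sided sign-flip permutation p = 1.53e-05, adjusted p = 9.16e-05 over 6 such tests). Chromosome length was taken as the end of the last region. The test does not hold constant where cytosines are dense or regions can be called, and whether this sets the ratio was not tested. The 970 and 880 CHH regions lower in bagged skin gave a ratio of 1.10, with more in the middle on 11 of 17 chromosomes (exact permutation p = 0.238). The ratios were 0.806 for higher and 0.962 for lower CG regions and 1.21 for higher and 1.30 for lower CHG regions, on fewer regions, and none of these 4 passed the threshold (lowest exact permutation p = 0.0813, adjusted p = 0.232). Differences between the ratios were not tested. Neighbouring higher CHH regions lay a median of 6655 bp apart.

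Regions of different contexts met more often than random placement gave. On the chromosomes, 226 of 1958 CG regions (11.5%) overlapped a CHH region, against a mean of 46.9 after 1000 circular shifts of the CG regions and a maximum of 72, a ratio of 4.82. For CHG and CHH regions 217 overlaps stood against a mean of 42.9. For CG and CHG regions 279 overlaps stood against a mean of 1.65, a ratio of 169. Of all CG regions, scaffolds included, 11.4% overlapped a CHH region, but 1.72% did when differences of at least 20 points were asked for in both contexts and 1.36% at 30 points, and for CHG regions the share went from 11.7% to 1.98% and 0.208%. At 20 points 5027 of the 50043 CHH regions were left, and the shifts were not repeated at these limits. Circular shifts do not hold constant where cytosines are dense or coverage is sufficient for a call. A common preference of the contexts for callable sequence may therefore account for part of these ratios, and that was not tested.

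Close to each other without overlapping, CG and CHH regions went in opposite directions more often than permuted directions did. Within 500 bp, 97 of 346 pairs (28.0%, exact binomial interval 23.4 to 33.1) shared direction against 40.9% under block permutation (permutation p = 0.0001, the smallest possible, adjusted p = 0.0003 over 12 tests by distance). For CHG and CHH pairs it was 129 of 348 (37.1%) against 50.9% (permutation p = 0.0001, adjusted p = 0.0003). With a gap over 500 and up to 2000 bp the CG and CHH pairs stood at 40.5% against 41.0% (permutation p = 0.8075) and the CHG and CHH pairs at 46.5% against 50.9% (permutation p = 0.0222, adjusted p = 0.0444). Overlapping pairs of the same contexts had the opposite tendency, with 83.7% and 94.2% in the same direction. Leaving them out removes mostly pairs of the same direction from the close pairs, and the permutation does not allow for this. The excess of opposite directions is therefore not read as a trait of all close pairs. A rule of the caller that joins or parts neighbouring regions was not examined, and no explanation was tested.

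Most CHH regions were higher and most CG regions lower in bagged skin. For incomplete bisulfite conversion in the bagged libraries, uniform over the genome, the median CHH gain would need a failure rate of 13.3%. Of all regions, 22.8% had a bagged level below that rate (17.5 to 25.4% on single chromosomes), as had 19.4% of the higher CHH regions. The rate was taken from regions called for their gain, so it is subject to selection, and the comparison cannot decide. Different room to rise or fall and the number of cytosines are argued against as the whole cause. The CHH share of higher regions was 50.02 points above that of CG at a mean level of 30 to 50% (45.2 to 54.7). Among regions of 10 to 20 cytosines it was 49.6 points above the CG share (45.7 to 53.5). These bounds join opposite ends of the separate exact binomial intervals of both shares and cover counting error only. Level did go with direction within CG context, where 73.9% were higher under 10% (CHH 90.8%), 42.9% from 10 to 30% and 28.2% from 70 to 100%, so it may account for part of the CG split. A smaller or uneven failure of conversion and a difference in depth were not examined. They and a uniform failure stay open beside the effect of bagging itself, the difference that the design names.

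CG and CHG regions also shared direction in pairs that did not overlap. A region that overlapped another region of the other context was kept in these pairs, so their shares are not independent of the overlaps. The share was 91.5% of 82 pairs with a gap of 1 to 500 bp, 76.3% of 80 pairs over 500 and up to 2000 bp apart and 55.9% of 340 pairs over 2000 and up to 20000 bp apart, where permuted directions gave 48.8% (permutation p = 0.0162, adjusted p = 0.0389, and 0.0202 and 0.0181 unadjusted with bins of 100 kb and 5 Mb). Beyond that, up to 100000 bp, it was 52.9% against 50.2% (permutation p = 0.0549). Sequenced fragments shared between the contexts do not reach over 2 kb, so they are argued against for the pairs farther apart, where the excess was small. For overlapping pairs and those within a fragment length, shared molecules may still account for the common direction, and no read counts were used here to examine it.

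CG and CHG regions on unplaced scaffolds were more often higher in bagged skin than those on chromosomes: 105 of 166 (63.3%) against 44.0%. A single scaffold was not the reason, since the gap of 19.2 points stayed at 16.6 points or more when each of the 65 scaffolds was left out, the smallest value without scaffold_278.2, which held 16 of the regions. Nor were the levels of the regions, since with chromosome regions weighted to the contexts and mean levels of the scaffolds the gap was 19.4 points (bootstrap over scaffolds 11.0 to 27.9). Higher regions were the majority on 38 scaffolds and the minority on 20. What sequence the scaffolds hold was not analysed here, so repeats collapsed in the assembly and a biological difference both remain open.

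A few regions have unusual values in the authors' deposited table. The CHH regions on chromosome 9 from 18580128 to 18580504 and on chromosome 14 from 19545127 to 19545346 are lower in bagged skin by the deposited means (-5.19 and -7.13 points) but have positive area statistics, 35.8 and 38.8. The longest region, on chromosome 13 from 19296051 to 19300914, spans 4864 bp with 142 CHH cytosines, and on chromosome 8 a CHH region from 25922939 to 25926285 spans 3347 bp with 6 cytosines, where the median CHH region has a cytosine every 3.52 bp.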
